A study of Mus musculus with 6 samples.

How the data were processed

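Gene expression was measured by bulk RNA-seq of dorsal root ganglia in 6 libraries. Of these, 3 came from Hdac2 conditional knockout mice and 3 from littermates with floxed Hdac2 but without Cre, called WT. Groups and replicate numbers came from the sample titles, and the 6 columns of the table were matched to samples by name. RNA was extracted from frozen ganglia with Trizol, per the labels' protocols. Whether each library came from 1 mouse or from pooled ganglia is not given in the sources used here, so p-values measure the spread between these libraries.

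HISAT2, SAMtools, featureCounts and DESeq2 were used with mm10, per the submitters' processing notes; versions, the annotation, strand setting and counting options are not given in the sources used here. Without strand information, reads of overlapping and antisense genes cannot be told apart. The deposited signal values were not whole numbers: they were gene read counts divided by 1 factor per library. Dividing each column by its smallest value above 0 gave whole reads for 100% of values within a tolerance of 0.01. DESeq2 size factors recomputed from these reads were 1.13, 0.672 and 0.978 for WT 1, 2 and 3 and 0.990, 1.02 and 1.43 for Hdac2 cKO 1, 2 and 3, equal to the deposited factors within 2.2e-06 of their ratio. The table had 54532 gene rows, of which 17327 were at 0 in all libraries; 54409 identifiers matched GENCODE release M21 (GRCm38, the assembly of mm10), which gave symbols, coordinates, lengths and GC content. All 37 mitochondrially encoded genes were at 0 in all libraries, so the list of those genes was not tested.

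Total reads per library ranged from 18943595 to 42070531 and genes detected from 24458 to 29181. Among genes with 1 to 20 reads the share of even counts was 63.2, 42.4 and 60.2% in WT 1, 2 and 3 and 62.2, 64.4 and 60.7% in Hdac2 cKO 1, 2 and 3. WT 2 thus lacked the excess of even counts that the other libraries held. The cause was not tested, and its effect on the values is not known.

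The design fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test. As the deposited values were not counts, the main test was limma 3.58.1 with R 4.3.3, on log2 (value + 1), with an intensity trend and robust variances, for the 18410 genes at 10 or more in at least 3 libraries. These settings were chosen after the values were seen and before any fit. Fold changes on this scale understate changes of low genes. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists, 40 fixed before the data were examined, were tested with camera at a preset correlation of 0.01; 39 had at least 3 tested members. Camera was repeated with an estimated correlation, and fry was run. Alternatives chosen before the data were examined were edgeR 4.0.16 with RLE scaling, DESeq2 1.42.0, limma-voom, scaling by library totals, 2 filters, the replicate block, a fold threshold and leaving out each library. Chosen after seeing the data were edgeR with TMM scaling on recovered reads, with and without block, DESeq2 with block, TMM scaling in limma, pseudocounts of 0.5 and 5, gene length and GC corrections with and without block, array weights, a sex term from Y-linked reads, and leaving out both libraries numbered 3.

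Named genes followed a rule fixed before the data were examined: 8 genes of the study's question; the genes with the largest changes among those past the threshold, or, as none passed, the 5 with the smallest p in each direction as values only; and up to 4 members per list that passed, or up to 2 as values only. Acta1, Myh4, Il31ra and Xist lie outside it and were chosen after their values were seen, as were the genes so marked elsewhere.

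Replicate numbers were checked for pairing. Deviations from the group means correlated across genes between same-numbered libraries by 0.40, 0.15 and 0.42 for numbers 1, 2 and 3, all over 0.1, so by a rule set before the fits the numbers were treated as pairing the libraries, from the data and not from the labels. The pairing was not specific to the numbers throughout: WT 1 and Hdac2 cKO 2 correlated by 0.34, more than the libraries numbered 2 did. Deviations within a group sum to 0. The likeness of the libraries numbered 3 therefore makes correlations among numbers 1 and 2 positive on balance. The check thus speaks at most for the libraries numbered 3, and results with the replicate block rest on an uncertain pairing. No replicates agreed within sampling noise: the chi-square per gene was at least 17.5 in every pair of libraries.

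The scripts were tested on simulated data with the real means and library sizes and 200 changed genes, 100 changed 2-fold and 100 changed 4-fold. At a spread set from these libraries (simulated biological coefficient of variation 0.537, against a common one of 0.487 in the real data) limma gave median log2 fold changes of 1.03 and 1.99 over 17779 genes, edgeR recovered 1% and 40% over 17823 genes, and limma made 4 false calls. At a low spread limma recovered 89% and 96%. Simulated genes were drawn independently, each with the same spread in all libraries, so neither an outlying library nor deviations shared between genes were simulated.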

Results

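Bulk RNA-seq was read from dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of C57BL/6 mice aged 8 weeks. A conditional knockout of Hdac2 (Hdac2 cKO, 3 libraries) carried Cre recombinase under the Advillin promoter, which is active in primary sensory neurons, together with floxed Hdac2 alleles. Littermates without Cre (called WT, 3 libraries) served as controls, and the labels give them the same floxed Hdac2 genotype (hdac2-flop++). The groups thus also differed by Cre itself, and no group carried Cre without floxed Hdac2. Reads assigned to genes totalled 31338593, 18943595 and 29107735 in WT libraries 1, 2 and 3 and 27787407, 28480554 and 42070531 in Hdac2 cKO libraries 1, 2 and 3. The study asked whether loss of HDAC2, a histone deacetylase, in sensory neurons alters expression of Cacna2d1, which encodes the calcium channel subunit α2δ-1, and of NMDA receptor genes linked to chronic pain. All values below are read counts divided by a size factor per library (normalised read counts), and log2 fold changes are Hdac2 cKO minus WT on the log2 (value + 1) scale.

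Hdac2 (ENSMUSG00000019777, mm10 chromosome 10, 36974544 to 37001889, plus strand) was lower in every knockout library. It stood at 2816, 1715 and 3498 normalised read counts in WT 1, 2 and 3, and at 499.1, 371.5 and 535.0 in Hdac2 cKO 1, 2 and 3. The means were 2676 ± 899 (SD, n = 3) and 469 ± 85.9 (SD, n = 3). The log2 fold change was -2.47 (SE 0.31), so that the knockout ganglia held 0.181 of the WT level. Whole-ganglion RNA also holds cells without Cre, and a gene-level count also takes reads from exons outside the deleted part. The ratio thus does not give the level left in sensory neurons. Hdac2 had the smallest p of all genes tested, but did not pass limma's test over all genes (adjusted p = 0.927). Adjusted over the list alone, among 18 histone deacetylase genes, it passed (limma adjusted p = 0.00137). DESeq2 called it over all genes (adjusted p = 6.5e-09). So did limma with array weights, which rest the WT mean mostly on WT 2 (adjusted p = 0.0017). Hdac1 (ENSMUSG00000028800), its close paralog, had a log2 fold change of 0.67 (SE 0.61), with overlapping groups and limma adjusted p = 0.927. The log2 fold change of Hdac1 was 0.03 without WT 3 and 1.16 without WT 1.

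**Figure D1:**
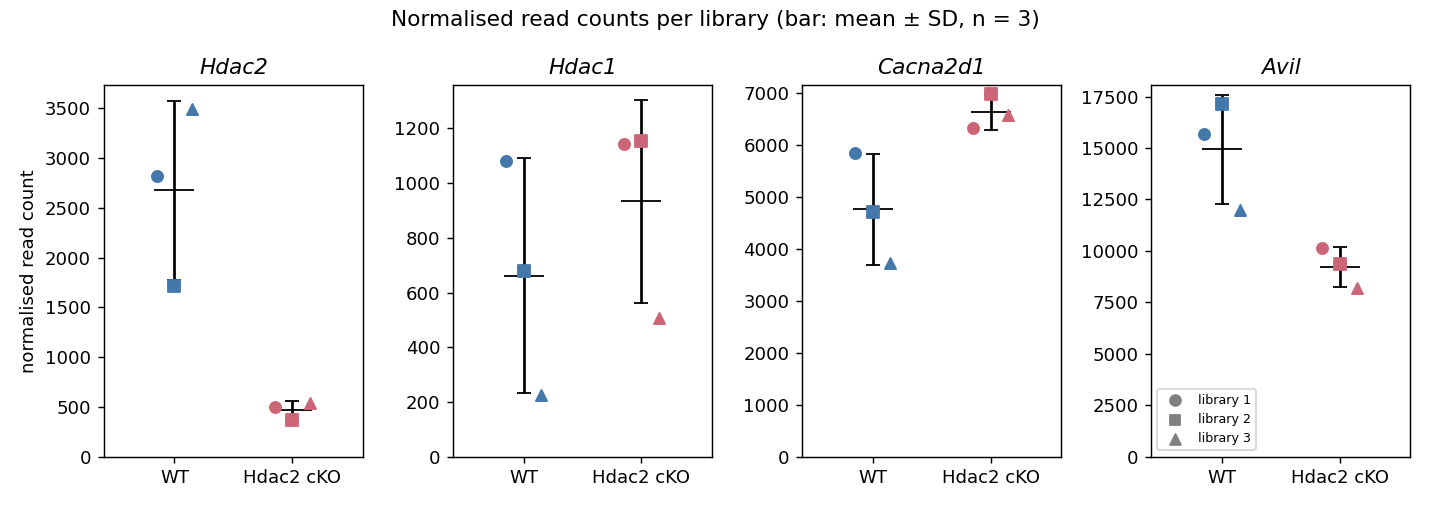
Normalised read counts (y axis, from 0) of Hdac2, Hdac1, Cacna2d1 and Avil in the 3 WT and 3 Hdac2 cKO libraries; symbols mark library numbers and bars give the mean ± SD. The Hdac2 cKO libraries lie between 371.5 and 535.0 for Hdac2, below all WT libraries, and between 6326 and 7000 for Cacna2d1, above all WT libraries.

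Cacna2d1 (ENSMUSG00000040118, mm10 chromosome 5, 15934691 to 16374511, plus strand) stood at 5862, 4708 and 3725 normalised read counts in WT 1, 2 and 3 and at 6326, 7000 and 6579 in Hdac2 cKO 1, 2 and 3. The means were 4765 ± 1070 (SD, n = 3) and 6635 ± 341 (SD, n = 3). The log2 fold change was 0.50, which is a ratio of 1.41, with a 95% confidence interval of the log2 fold change from -0.01 to 1.02. The groups did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Cacna2d1 did not pass over all genes (limma adjusted p = 0.927). Without WT 3 the log2 fold change was 0.34, and with gene length correction 0.31.

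Avil (ENSMUSG00000025432, mm10 chromosome 10, 127000709 to 127020994), the gene whose promoter drives Cre, was lower in every knockout library. Its means were 14943 ± 2655 in WT and 9231 ± 969 in Hdac2 cKO (SD, n = 3 each), and its log2 fold change was -0.68 (SE 0.21; limma adjusted p = 0.927). With array weights it was called at -0.81 (adjusted p = 0.0119). Of the NMDA receptor subunit genes, Grin1, Grin2a, Grin2b and Grin2d overlapped between groups. Grin1, the obligatory subunit, stood at 2560 ± 1139 in WT and 1798 ± 269 in Hdac2 cKO (SD, n = 3 each), with a log2 fold change of -0.43 (SE 0.34). Grin2d had a log2 fold change of -0.48 (SE 0.37) and Grin2b of -1.90 (SE 1.22). Without WT 3 these were -0.09 for Grin1, -0.24 for Grin2d and -0.63 for Grin2b, and without WT 1 they were -0.73 for Grin1 and -0.76 for Grin2d. With GC correction they were -0.20 for Grin1 and -0.02 for Grin2d. Grin2a, at means of 39.3 and 11.1 normalised read counts, had a log2 fold change of -0.31 (SE 1.47), which became 1.23 without WT 3. None of these passed. Grin3a, a modulatory subunit, was higher in every knockout library, at 762 ± 9.05 against 512 ± 107 (SD, n = 3 each), and did not pass either (limma adjusted p = 0.927).

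No gene of 18410 passed limma's test at an adjusted p of 0.05, and the smallest adjusted p was 0.927. At an unadjusted p under 0.05 there were 341 genes, 161 higher and 180 lower in Hdac2 cKO, fewer than the 920.5 expected by chance. Groups did not overlap for 1572 genes, 8.54% of those tested, against 10% expected by chance. By other tools, edgeR on the recovered reads called 0 genes, limma-voom 0 and DESeq2 23, of which 3 were higher and 20 lower. With the replicate number as a block, which pairs the libraries, limma called 0 genes and DESeq2 60. Array weights raised limma's count to 567 genes, 311 higher and 256 lower. The weights were 0.670, 4.17 and 0.101 for WT 1, 2 and 3, so the WT mean rested mostly on WT 2. WT 2 had the fewest reads and lacked the excess of even counts. Weights were 2.42, 3.65 and 0.402 for Hdac2 cKO 1, 2 and 3. Without both libraries numbered 3, limma called 5 genes. In data simulated with the spread of these libraries, limma recovered 1% of genes changed 2-fold and 40% of genes changed 4-fold. DESeq2 recovered 13% and 67% but with 62 false calls. The simulated genes varied independently and no simulated library stood apart as WT 3 does, so these rates need not hold for the real data.

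The genes with the smallest p, given as values only, were the following. Among those higher in Hdac2 cKO, Fgf1, a fibroblast growth factor, stood at 10825 ± 809 against 4179 ± 1786, Chrna3, a nicotinic acetylcholine receptor subunit, at 640 ± 68.2 against 176 ± 132, and Slc6a19, a neutral amino acid transporter, at 1050 ± 221 against 455 ± 49.9 (SD, n = 3 each). Slc5a5, the sodium iodide symporter, had a log2 fold change of 1.38 (SE 0.35) and the lincRNA Gm48898 of 2.48 (SE 0.51). Among those lower, Rnf26, a RING finger gene, stood at 5.19 ± 0.360 against 106 ± 58.8 and Des, the muscle intermediate filament desmin, at 111 ± 32.1 against 468 ± 85.6 (SD, n = 3 each). Ttn, the giant sarcomere protein titin, had a log2 fold change of -3.01 (SE 0.50), and Trdn, triadin of the muscle calcium release complex, of -4.24 (SE 0.74). DESeq2 called Fgf1, Slc6a19 and Gm48898 as higher and Hdac2, Rnf26, Des, Ttn and Trdn as lower. DESeq2 also called lower the muscle genes Myh7 and Tcap, the only 2 of its 23 calls in the muscle list fixed beforehand, and Mag, a myelin glycoprotein. That list does not hold every muscle gene. Outside it, Des, Ttn and Trdn and the muscle genes Actc1, Tpm2, Nrap, Ckmt2, Igfn1 and Vgll2 were called lower, so muscle genes made up much of the lower calls. The other lower calls of DESeq2 were C1ql4, Olfr920, Col26a1, Ddn, Gm36356 and Gm10167. These, and Actc1, Tpm2, Nrap, Ckmt2, Igfn1 and Vgll2, were named after their values were seen.

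Skeletal muscle genes had the largest median difference of the 39 lists in the main test, close to that of sex-linked genes (-3.40), which was larger in some other settings. All 18 tested members were lower in Hdac2 cKO, with a median log2 fold change of -3.50, and the list shifted lower in limma's camera test (adjusted p = 4.3e-25). With an estimated correlation the adjusted p was 0.424. By limma 13 members passed and fell adjusted over the list alone, and 0 did over all genes. DESeq2 called the members Myh7 (adjusted p = 0.00297) and Tcap (adjusted p = 0.00712) lower over all genes. Tcap, a sarcomere Z-disc protein, stood at 29.0 ± 29.0 normalised read counts in Hdac2 cKO against 325 ± 117 in WT, and Myh4, a fast myosin heavy chain, at 67.4 ± 92.5 against 762 ± 579 (SD, n = 3 each). Myh4 was chosen after its values were seen, as was Acta1, skeletal actin. Acta1 stood at 2877, 1336 and 81.8 in WT 1, 2 and 3 and at 69.7, 323 and 11.2 in Hdac2 cKO 1, 2 and 3. Its groups thus overlapped. It was lower in the knockout library of each same-numbered pair and was called by DESeq2 with the replicate block (adjusted p = 1.2e-08). As that pairing is uncertain and was read from these same data, this call adds no independent support.

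Markers of myelinating Schwann cells, the glia that wrap large axons, shifted lower as well. Of 23 tested members 20 were lower, with a median log2 fold change of -0.50 (camera adjusted p = 1.1e-07, and adjusted p = 0.424 with an estimated correlation). Without WT 1 the median was -0.22 (camera adjusted p = 0.004). By limma 0 members passed, either adjusted over the list alone or over all genes. Mag stood at 831 ± 78.9 in Hdac2 cKO against 1466 ± 78.3 in WT, and Pmp22, a compact myelin protein, at 47497 ± 9431 against 88116 ± 18410 (SD, n = 3 each), without overlap. Markers of non-myelinating Schwann cells had a median log2 fold change of 0.11 and did not shift (camera adjusted p = 0.422), and those of satellite glia had one of -0.16 (camera adjusted p = 0.26).

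**Figure D2:**
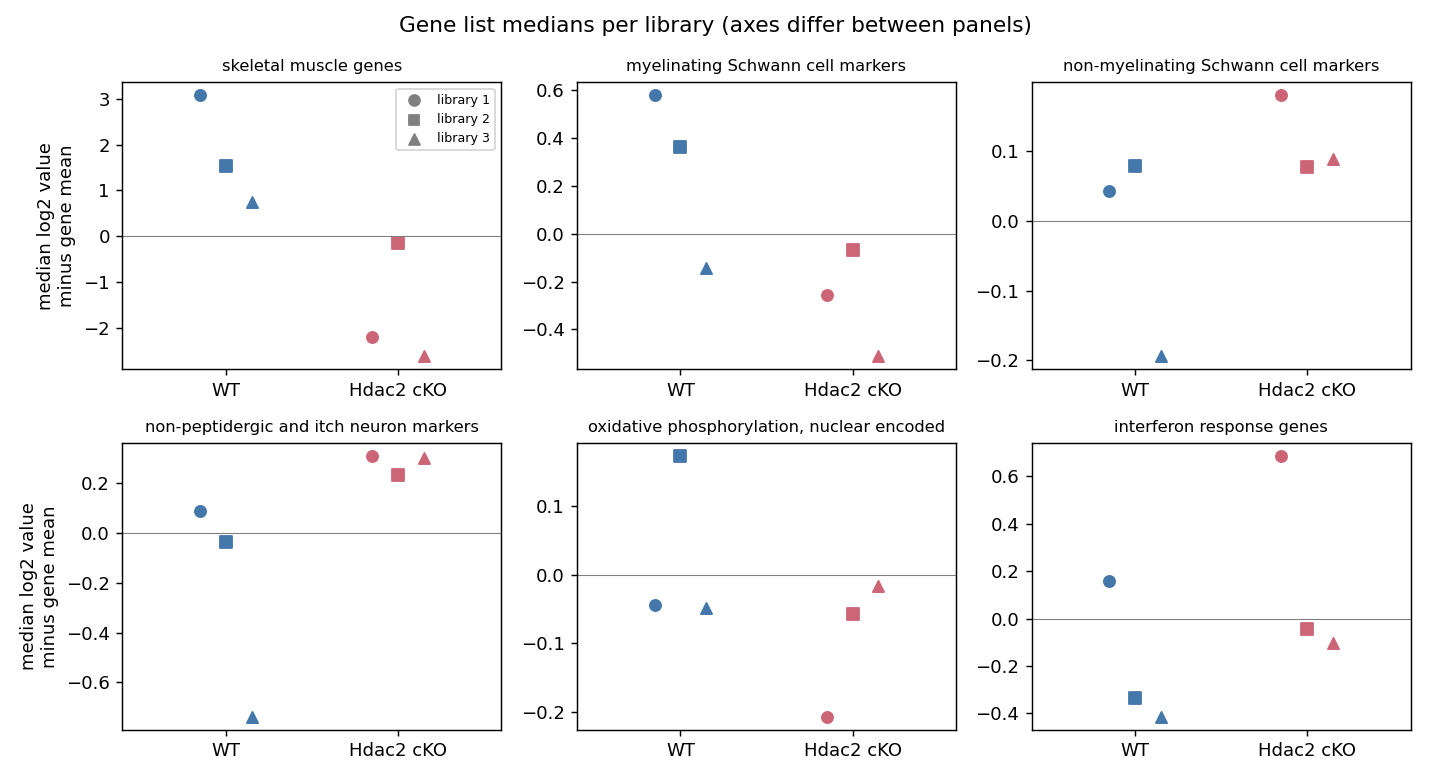
Median over the members of 6 gene lists of the log2 value minus the gene's mean over the 6 libraries (y axis, log2 units, scale differing between panels), per WT and Hdac2 cKO library; symbols mark library numbers. The skeletal muscle median lies between 0.75 and 3.07 in WT libraries and between -2.60 and -0.15 in Hdac2 cKO libraries.

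Of the neuronal lists, 3 shifted higher by camera, and each of these calls was lost with an estimated correlation (adjusted p = 0.564 for all 3). Markers of non-peptidergic and itch-sensing neurons had 22 of 28 members higher, a median log2 fold change of 0.51 and adjusted p = 8.6e-05. Within it Nts, the neuropeptide neurotensin, had a log2 fold change of 1.99 (SE 0.50), and Osmr and Il31ra, which together form the interleukin-31 receptor, of 1.22 (SE 0.38) and 1.68 (SE 0.54), Il31ra chosen after its values were seen. WT 3 held the lowest median of this list, and the list median was 0.20 without WT 3 (camera adjusted p = 0.00178) and 0.17 without both libraries numbered 3 (camera adjusted p = 0.0149). Voltage-gated sodium channels had 12 of 14 members higher, a median of 0.54 and adjusted p = 0.0141. The median was 0.16 without WT 3 (adjusted p = 0.0341), and with gene length correction it was 0.34 and the call was lost (adjusted p = 0.0695). Scn9a, a channel needed for pain, stood at 12192 ± 1327 against 7087 ± 3476 (SD, n = 3 each), a log2 fold change of 0.92 that was 0.47 without WT 3. Presynaptic release genes had 26 of 36 members higher, a median of 0.19 and adjusted p = 0.0323, and this call was lost without WT 1 (adjusted p = 0.192), WT 3 (0.141), Hdac2 cKO 1 (0.0541) or Hdac2 cKO 3 (0.114), and with gene length correction (0.153) or without both libraries numbered 3 (0.149). With array weights the median turned to -0.01 (adjusted p = 0.608). Of these 3 lists no member passed by limma, either adjusted over the list alone or over all genes. DESeq2 with the replicate block, an alternative chosen after seeing the data, called Nts (adjusted p = 1.2e-05), Il31ra (0.0034), Osmr (0.0103) and Scn2b (0.0486), a sodium channel beta subunit, as higher.

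Histone acetyltransferase genes had 16 of 17 members higher, a median log2 fold change of 0.25 and camera adjusted p = 0.0141 (adjusted p = 0.564 with an estimated correlation). The call was lost without WT 3 (adjusted p = 0.292), without both libraries numbered 3 (0.132), with array weights (0.0689) and with gene length correction. Interferon response genes had 25 of 32 higher, a median of 0.26 and adjusted p = 0.0226 (adjusted p = 0.83 with an estimated correlation). This call was lost without WT 2 (adjusted p = 0.448), without Hdac2 cKO 1 (0.983) and with a sex term (0.11). Nuclear-encoded oxidative phosphorylation genes had 31 of 47 lower, a median of -0.17 and adjusted p = 0.0026 (adjusted p = 0.564 with an estimated correlation), and lost the call without WT 2 (median 0.003, adjusted p = 0.123) and with gene length correction. Endothelial and mural cell markers had 16 of 25 lower, a median of -0.13 and adjusted p = 0.0141 (adjusted p = 0.564 with an estimated correlation), lost with a turned direction without WT 1 (median 0.03, adjusted p = 0.518) and without Hdac2 cKO 3 (median 0.04, adjusted p = 0.144), and lost with array weights (adjusted p = 0.108). In it Des alone passed adjusted over the list alone (limma adjusted p = 0.0085). Hox genes, which set body position, had 20 of 30 lower, a median of -0.18 and adjusted p = 0.0323 (adjusted p = 0.564 with an estimated correlation). The Hox call was lost without WT 2 (adjusted p = 0.401), WT 3 (0.14), Hdac2 cKO 1 (0.109) or Hdac2 cKO 2 (0.11), and with a sex term (0.0672), gene length correction (0.121) or GC correction (0.0713).

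The other 29 lists did not shift. The histone deacetylase family came nearest, with 12 of 18 members lower, a median log2 fold change of -0.25 and camera adjusted p = 0.0627, and passed with the replicate block (adjusted p = 0.0326); with an estimated correlation the adjusted p was 0.564. This list holds the deleted gene Hdac2 itself. The corepressor complexes that hold HDAC1 and HDAC2 had a median of 0.04, voltage-gated calcium channel subunits 0.06 and ionotropic glutamate receptors 0.06. Among channel and receptor lists, potassium channels had a median of 0.16, sensory transduction channels 0.29, inhibitory G protein-coupled receptors and opioid peptides 0.21, and GABA-A and glycine receptors 0.31; the first and second of these passed with the replicate block (adjusted p = 0.0371 and 0.0326), but not with an estimated correlation and no block (adjusted p = 0.876 and 0.564). Pan-neuronal markers had a median of 0.10, peptidergic nociceptor markers 0.13, C-low-threshold mechanoreceptor markers 0.02, large-diameter neuron markers -0.02, and nerve injury genes 0.12. Calb2, calretinin of large-diameter neurons, stood at 736, 697 and 1596 in WT 1, 2 and 3 and at 85.9, 96.3 and 487 in Hdac2 cKO 1, 2 and 3 (log2 fold change -2.55, SE 0.69), and was called lower by DESeq2 with the replicate block (adjusted p = 9.8e-09). Macrophage markers had a median of 0.37 and lymphocyte and granulocyte markers of 0.61, and both passed with the replicate block (adjusted p = 0.0326 and 0.0211), as did sex-linked genes (median -3.40, adjusted p = 0.0222). With an estimated correlation and no block the adjusted p was 0.876 for both immune lists and 0.564 for sex-linked genes. The sex-linked difference follows the sex of the libraries. Y-linked genes summed to 3649.5, 5698 and 3993 normalised read counts in WT 2, WT 3 and Hdac2 cKO 2, and to at most 7.06 in the others. The immune medians turned to -0.09 for macrophages without WT 3 and -0.14 for lymphocytes and granulocytes without Hdac2 cKO 2. Relative to the gene means, lymphocyte and granulocyte medians were 1.57, -0.94 and -1.24 in WT 1, 2 and 3. They were 1.31, 1.64 and -1.42 in Hdac2 cKO 1, 2 and 3. Macrophage medians were 0.63, -0.07 and -1.07 against 0.76, 0.63 and -0.92. These lists, and erythroid genes, thus set WT 1, Hdac2 cKO 1 and Hdac2 cKO 2 above the other libraries, across the groups. Medians were 0.61 for erythroid genes, -0.15 for fibroblast, -0.41 for adipocyte, 0.39 for bone and cartilage, and -0.05 for spinal cord and brain cell genes, 0.22 for cytokines and chemokines, 0.04 for immediate early genes, 0.07 for cytosolic ribosomal proteins, -0.32 for replication-dependent histones, -0.01 for cell cycle genes and -0.04 for cholesterol and fatty acid synthesis.

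The libraries differed from one another more than the groups did. The first principal component held 62.7% of the variance and set WT 3 (score 184) apart from the other 5 libraries, and Hdac2 cKO 3 stood apart on the second. WT 3 deviated from the gene medians by a mean of 1.07 log2 units, against at most 0.475 in any other library, and had 0 reads for 449 genes that all other libraries held at 10 or more. Both sexes were present in each group: Y-linked transcripts were read in WT 2, WT 3 and Hdac2 cKO 2. Xist, chosen after its values were seen, stood at 11489, 11.9 and 192 in WT 1, 2 and 3 and at 10623, 1.97 and 7474 in Hdac2 cKO 1, 2 and 3.

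**Figure D3:**
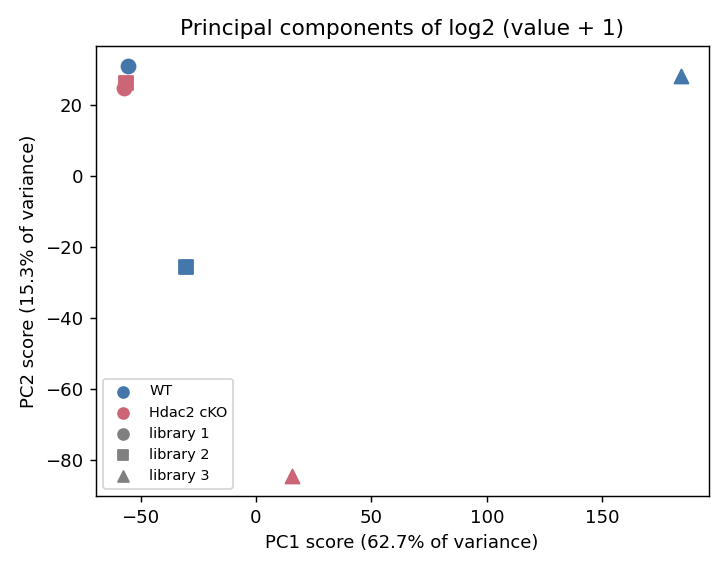
Scores of the 6 libraries on the first and second principal components of log2 (value + 1) over 18410 genes, with the share of variance on each axis; colour gives the group and symbol the library number. WT 3 lies at 184 on the first component and Hdac2 cKO 3 at -84.5 on the second.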

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

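Alternatives with TMM scaling, edgeR with TMM or its block, DESeq2 with block, other pseudocounts, GC or length corrections, array weights, the sex term or both libraries numbered 3 left out were chosen after seeing the data. A gene length correction had been chosen beforehand only if the file gave lengths, which it did not, so annotated lengths were used. The cause of a difference between settings was not tested. Limma's count of changed genes was 0 with all filters, scalings, pseudocounts, corrections, the replicate block, the sex term and each library left out in turn, as it was with limma-voom and with edgeR, and requiring at least a 2-fold change left it at 0. DESeq2 called 23 genes (3 higher, 20 lower), DESeq2 with replicate block 60 (25 and 35), array weights 567 (311 and 256), and the 4 libraries without both numbered 3 gave 5 (4 and 1). Hdac2 kept its direction in every setting and passed in DESeq2 at -2.51, in DESeq2 with replicate block at -2.47 and with array weights at -2.13; leaving out each library gave -2.76 to -2.24, none past the threshold. Cacna2d1 was higher in every setting, at 0.34 to 0.66 when each library was left out, and passed in none.

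The replicate block left the fold changes as they were in limma, raised the shifted lists from 10 to 16, adding histone deacetylases (median log2 fold change -0.25), potassium channels (0.16), sensory transduction channels (0.29), macrophages (0.37), lymphocytes and granulocytes (0.61) and sex-linked genes (-3.40), and changed no call of a single gene in limma. Lists numbered 6 with gene length correction, 17 without both libraries numbered 3, 8 to 14 when each library was left out, 0 with an estimated correlation and 0 by fry. Skeletal muscle, myelinating Schwann cell and non-peptidergic neuron lists were called in all 21 limma settings run at the preset correlation, the main test included. Named genes other than Hdac2 and Cacna2d1 gave 2205 values under alternatives. Of these 2130 kept their direction and side of the threshold, 70 passed and 5 changed sign. The 70 came from array weights (40), DESeq2 (10), DESeq2 with block (16) and leaving out both libraries numbered 3 (4). Of 780 list medians 609 kept their sign and side of the threshold, 60 kept their sign and passed, and 25 kept it and lost their call. Another 86 changed sign, a few of them with a call gained or lost. WT 2 had the fewest reads, at 18943595. It lacked the excess of even counts of the other libraries, so the totals need not measure depth alike.

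Other settings moved list calls and the signs of medians near 0 or with a wide spread; medians stand in parentheses. Without a filter calls were gained for potassium channels (0.16), sensory transduction channels (0.26), inhibitory G protein-coupled receptors (0.22), lymphocytes and granulocytes (0.85) and spinal cord and brain (-0.59), and signs changed for GABA-A and glycine receptors (-0.0026), immediate early genes (-0.0090) and replication-dependent histones (0.16). The stricter filter gained adipocyte genes (-0.64) and turned immediate early genes (-0.0090). TMM scaling turned large-diameter neurons (0.032), cell cycle genes (0.040) and cholesterol synthesis (0.0059). Gene length correction lost histone acetyltransferases (0.19), sodium channels (0.34), presynaptic release (0.12), Hox genes (-0.16) and oxidative phosphorylation (-0.11), and gained histone deacetylases (-0.27). In the replicate block with gene length correction histone acetyltransferases (0.19) and presynaptic release (0.12) were lost too and histone deacetylases (-0.27) gained, along with macrophages (0.38), lymphocytes and granulocytes (0.70) and sex-linked genes (-3.55). Length correction with or without block turned corepressor complexes (-0.0041), calcium channel subunits (-0.0077), ionotropic glutamate receptors (-0.12), immediate early genes (-4.9e-06) and cell cycle genes (0.037). GC correction gained potassium channels (0.21), sensory transduction channels (0.23) and inhibitory G protein-coupled receptors (0.25) and lost Hox genes (-0.15). In the replicate block with GC correction potassium channels (0.21) and sensory transduction channels (0.23) were gained, with macrophages (0.32), lymphocytes and granulocytes (0.71) and sex-linked genes (-3.63). GC correction with or without block turned ionotropic glutamate receptors (-0.075), large-diameter neurons (0.068), spinal cord and brain (0.0076), cell cycle genes (0.044) and cholesterol synthesis (0.038).

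Array weights gained GABA-A and glycine receptors (0.23), macrophages (0.46), lymphocytes and granulocytes (2.15) and erythroid genes (2.48), lost histone acetyltransferases (0.15) and endothelial and mural cells (-0.12) and turned Grin2a (1.46), Adipoq (0.20), calcium channel subunits (-0.11), presynaptic release (-0.013, call lost), pan-neuronal markers (-0.13), immediate early genes (-0.66, called), adipocyte genes (0.46), ribosomal proteins (-0.069) and cell cycle genes (0.58, called). Without both libraries numbered 3 calls were gained for sensory transduction channels (0.17), inhibitory G protein-coupled receptors (0.19), GABA-A and glycine receptors (0.26), peptidergic nociceptors (0.23), large-diameter neurons (-0.17), macrophages (0.40), lymphocytes and granulocytes (1.20) and erythroid genes (1.57) and lost for histone acetyltransferases (0.14) and presynaptic release (0.040). Signs changed there for Grin2a (1.12), calcium channel subunits (-0.044), ionotropic glutamate receptors (-0.042), pan-neuronal markers (-0.036), immediate early genes (-0.28, called), bone and cartilage genes (-0.27), spinal cord and brain (0.15), ribosomal proteins (-0.038) and cell cycle genes (0.36). The sex term gained histone deacetylases (-0.22), nerve injury genes (0.20), adipocyte genes (-0.50) and sex-linked genes (-1.01), lost interferon response (0.13) and Hox genes (-0.083) and turned ionotropic glutamate receptors (-0.020), spinal cord and brain (0.10) and cell cycle genes (0.091).

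Leaving out each library in turn changed a call or a sign for the following, with the range over the 6 fits. It ran from -1.51 to 1.23 for Grin2a, -0.86 to 0.0082 for adipocyte genes, -0.24 to 0.84 for bone and cartilage genes, -0.11 to 0.37 for C-low-threshold mechanoreceptors, -0.24 to 0.29 for cell cycle genes, -0.15 to 0.12 for cholesterol synthesis, -0.026 to 0.17 for ribosomal proteins, -0.26 to 0.040 for endothelial and mural cells, -0.16 to 2.65 for erythroid genes and -0.54 to 0.36 for fibroblasts. It ran from 0.13 to 0.36 for GABA-A and glycine receptors, -0.29 to 0.017 for histone deacetylases, -0.022 to 0.074 for corepressor complexes, 0.13 to 0.41 for histone acetyltransferases, -0.39 to -0.12 for Hox genes, -0.41 to 0.43 for immediate early genes, -0.035 to 0.59 for cytokines, 0.038 to 0.48 for interferon response, -0.035 to 0.11 for ionotropic glutamate receptors and -0.13 to 0.14 for large-diameter neurons. It ran from -0.14 to 1.86 for lymphocytes and granulocytes, -0.088 to 0.89 for macrophages, 0.087 to 0.20 for nerve injury genes, -0.0028 to 0.23 for non-myelinating Schwann cells, -0.32 to 0.0034 for oxidative phosphorylation, 0.065 to 0.29 for peptidergic nociceptors, 0.056 to 0.28 for presynaptic release, -0.40 to 0.076 for replication-dependent histones, -6.55 to -1.82 for sex-linked genes and -0.15 to 0.39 for spinal cord and brain.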

Other observations

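The tests of muscle co-variation, of the non-myelinating Schwann cell markers, of leaving out WT 3, and of depth and of GC content and gene length in WT 3 were chosen after their results or closely related values were seen, and the genes named in this part after their values; the other tests were written down before theirs were.

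Each of 3 genes near the major histocompatibility complex of chromosome 17 was lower in Hdac2 cKO 3 than in the other knockout libraries; the region as a whole was not tested. H2-Eb1 (chromosome 17, 34305867 to 34316674) stood at 116, 92.3 and 58.3 normalised read counts in WT 1, 2 and 3 and at 1359, 819 and 35.0 in Hdac2 cKO 1, 2 and 3. H2-T22 (36037128 to 36042747) stood at 127, 93.8 and 28.6 against 715, 783 and 81.8. Rps18, a ribosomal protein gene nearby (33951999 to 33956001), stood at 242, 308 and 1054 against 2603, 3515 and 401. Without both libraries numbered 3, these 3 genes and Fgf1 were called higher and Calb2 lower by limma. The ribosomal RNA-like transcript CT010467.1 stood at 23664 in WT 2 and between 234288 and 488337 in the other libraries. WT 3 held Xist at 6.46 CPM together with Y-linked transcripts, against 0.422 in WT 2 and 0.0702 in Hdac2 cKO 2.

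Skeletal muscle genes were lower in Hdac2 cKO by a median of -3.50 log2 units (SD 1.52 over members). GC content and gene length trends were argued against, as the median was -3.47 after GC correction and -3.58 after length correction. Muscle tissue carried along with the ganglia may account for it: the members varied together within groups, with an estimated inter-gene correlation of 0.466 against a median of 0.118 over the other lists. This was not peculiar to muscle, as immediate early (0.496), macrophage (0.473), lymphocyte and granulocyte (0.617), fibroblast (0.553), erythroid (0.621) and adipocyte genes (0.567) reached more, and Acta1 at 81.8 in WT 3 and 2877 in WT 1 stood in another ratio to Tnnt3 (284 and 1662). Of 10 splits of the libraries 1 gave a median as far from 0, the real one, with 2.97 the highest other. Among the 4 splits that part all 3 pairs, the real one included, the highest other was 2.16. These 10 splits are too few for a share under 0.05. An effect of the genotype stays open and was not tested, and 1 member, Pvalb, is also a marker of sensory neurons.

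Myelinating Schwann cell markers were lower by a median of -0.50 (SD 0.42 over members). The median of the non-myelinating markers lay 0.61 above, more than the SD of 0.33 over their members. This cannot decide on a lower share of all Schwann cells, as the non-myelinating list is not specific to them. Gap43, Ncam1, Gfra3 and Apoe also stand in lists of neurons or satellite glia used here, and Sox10 in the myelinating list. GC correction left the median at -0.58 and length correction at -0.47, which argues against these as the whole cause. High values in WT 3 were not the source. WT 3 held the lowest WT median of the list, -0.15 against 0.58 and 0.36 in WT 1 and 2. Leaving WT 3 out was thus bound to widen the difference, and gave -0.59. Over all 6 fits that leave out 1 library the median log2 fold change ran from -0.69 to -0.22, nearest to 0 without WT 1. Of 10 splits 2 gave a median as far from 0, with 0.55 the highest other against 0.50. Among the 4 splits that part all 3 pairs, the real one included, the highest other was 0.21. These 10 splits are too few for a share under 0.05. A lower share of all Schwann cells stays open. A lower share of myelinated axons with their myelinating cells and an effect of the genotype on myelin genes stay open too and were not tested.

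WT 3 stood apart from the other libraries. Low depth is argued against: thinned to 18943600 reads each, WT 3 had 299 genes at 0 that all others held at 10 or more, 42.7 times the next library's 7. GC content and gene length are argued against, since its mean deviation of 1.07 stayed at 1.05 after both corrections. Few starting molecules may account for it: 18.9% of genes at 20 to 50 in the other libraries were at 0 in WT 3 and 0.0166% of those at 1000 or more, but the other libraries reached up to 10.3% in the same range, so the bound set beforehand separated them poorly; at 50 to 100 the shares were 8.41% in WT 3 and at most 1.33% elsewhere. No biological explanation was tested.

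Counts of genes and lists were set against the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. By limma the real count was 0, so all 10 splits reach it by construction (highest other 4) and this decides nothing. By DESeq2 5 did (23, highest other 1372), with array weights 5 did (567, highest other 9381), and for shifted lists 7 did (10, highest other 13). Splits that call many times the real count by DESeq2 or with array weights point to a structure of the libraries that does not follow the groups. The 1372 DESeq2 calls came from setting WT 1, Hdac2 cKO 1 and Hdac2 cKO 2 against the other libraries. The real split parts all 3 same-numbered pairs. Among the other splits that do so the highest counts were 2 by DESeq2, 2 with array weights and 12 lists. Only 4 splits part all 3 pairs, the real one included, and the pairing was read from these same data, so this comparison decides nothing.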
